A study of Drosophila melanogaster with 6 samples.

How the data were processed

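Gene expression was measured in heads of female Drosophila melanogaster kept at 25 °C, on 6 Affymetrix oligonucleotide arrays. Per the labels' protocols, biotin-labelled cRNA was made from 3 µg of total RNA. The deposited values are on a log2 scale; RMA is named in the submitters' processing notes, its version is not given in the sources used here, and the scale was taken from the range of the values. RMA combines the probes of a probe set and sets the arrays to a common distribution, so a shift that all transcripts shared would not be seen, and dim probe sets are compressed towards the floor. For arrays, the number of samples limits the precision.

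Groups were taken from the sample labels: control at ZT3 (2 arrays), control at ZT15 (2 arrays), Tim-Fbl at ZT3 (1 array) and Tim-Fbl at ZT15 (1 array). ZT is zeitgeber time, the hour counted from lights-on. The labels give the replicate numbers but do not say whether replicates came from separate fly cultures, so the p-values measure only the spread between these samples, which may be technical. Of 18952 probe sets, 183 manufacturer's control probe sets were left out and 18769 were tested. The probe annotation gave exactly 1 symbol to 13647 of these, several to 402 and none to 4720, and the named ones stood for 11982 genes. Symbols were compared through gene identifiers with a RefSeq gene table of the assembly Release 6 plus ISO1 MT, which changed 0 symbols and left 103 identifiers unmatched, for which the annotation's name was kept. No genome coordinates are given, because the sources used here name no genome build for the arrays. No column of values was left unused.

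Values were used as deposited and tested per probe set with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The time effect in controls and the strain-by-time interaction came from a fit of the 4 group means to all 6 arrays, with 2 residual degrees of freedom, all from the control pairs. The strain effect came from an additive model of strain and time with 3 residual degrees of freedom. The single Tim-Fbl array of each time was assumed to vary like the control arrays, and the time difference within Tim-Fbl was given without a test of its own. Gene lists were fixed before the data were examined, as were the designs, the rule for named genes and most alternatives. Lists with at least 5 measured genes, 26 in all, were tested with limma's camera at a preset correlation of 0.01, using the probe set with the highest mean for each gene. The same test with an estimated correlation, and fry, were run beside it. With an estimated correlation that test has only the 2 or 3 residual degrees of freedom, so hardly any list could pass. Its large p-values therefore do not show that a list did not shift. Estimated correlations above the preset, such as 0.429 for the immune list in the interaction, also raised these p-values. Where the genes of a list vary together, p-values at the preset may be too small. Symbols of list members were matched to current symbols or synonyms.

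Named genes were fbl, tim and the clock genes with a known phase, and for each test the 10 with the largest rise and the 10 with the largest fall among probe sets past the threshold with 1 symbol, a mean log2 of at least 5 in the higher group and, except for the interaction, no overlap of the compared arrays. Where fewer than 10 passed, the largest changes at an unadjusted p under 0.05 followed, as values that did not pass. Each described list gave up to 4 members with the largest moderated statistic. Probe sets whose identifiers carry the manufacturer's suffix for shared sequence can also measure other transcripts; among those named these are vri, Clk, Pdp1, fbl, Slob, ND-19, PCB, Jra, Zip99C, bcd, Gat, CG11353 and CG8112.

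The functions were tested on simulated arrays built from the real probe set means, with variances drawn at random from limma's fitted distribution of variances. In each of 10 simulations 200 of 18769 probe sets were changed. Noise was independent between probe sets, and the simulated Tim-Fbl arrays varied like the control arrays. The single real Tim-Fbl array of each time cannot test that, so the shares found hold only under these assumptions. For the time effect, 27.9% of 1.5-fold, 93.9% of 2-fold and 99.7% of 4-fold changes were found. For the strain effect the shares were 71.0%, 97.0% and 99.8%. For the interaction they were 0.149%, 8.66% and 91.2%. Alternatives covered filters on probe sets with a mean log2 under 5 or 7, median subtraction, quantile normalization, cyclic loess, other variance models, 1 test per gene, a fold minimum of 1.5, the replicate number as a block, and leaving out each array in turn. For gene lists, the normalizations, the filter at 7, the block and the left-out arrays were added after seeing the data. Figures were drawn with matplotlib 3.10.9.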

Results

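Transcript levels were compared in female fly heads of a control strain and of a strain labelled Tim-Fbl in the RNAi field, collected at ZT3, in the morning, and at ZT15, in the early night. The controls had 2 arrays per time and Tim-Fbl had 1, so no Tim-Fbl value has a replicate of its own. Array medians lay between 5.46 and 5.51 log2 units. On every array the signal at the transcript's end exceeded that at its start. The excess was 5.28 to 5.72 log2 units for Act5C, 5.8 to 6.3 for GAPDH and 4.18 to 4.62 for eIF4a. For GAPDH it was 6.23 and 6.18 on the Tim-Fbl ZT3 and ZT15 arrays and 6.34 on control ZT15 replicate 2. The other control arrays had 5.8 to 6.0. For eIF4a the same 3 arrays had 4.62, 4.39 and 4.42, against 4.18 to 4.30 on the other control arrays. For Act5C the Tim-Fbl arrays, at 5.65 and 5.49, lay within the range of the controls. Replicate control arrays correlated at r = 0.996 at each time across probe sets, which are not independent replicates. The poly-A spike-in controls, measured by 12 probe sets, had a median of 6.76 on the Tim-Fbl ZT15 array, against a mean of 5.43 ± 0.312 (SD, n = 4) on the control arrays. The median 18S rRNA signal was 11.5 and 11.8 on the Tim-Fbl ZT3 and ZT15 arrays and 11.4 on control ZT15 replicate 2, against 12.3 to 12.7 on the other control arrays. Whether these differences between arrays bear on the strain effect was not tested.

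The strain's label holds the symbols of 2 fly genes, fbl and tim, and both were examined first. The level of fbl (fumble), which encodes pantothenate kinase, the enzyme of the first step of coenzyme A synthesis, was 3.36-fold lower in Tim-Fbl (log2 difference -1.75 ± 0.081 SE, limma adjusted p = 5.57e-05). It was 7.47 and 7.49 on the Tim-Fbl arrays at ZT3 and ZT15, against 9.27 ± 0.016 and 9.19 ± 0.115 (SD, n = 2) in controls at the same times. The other measured genes of coenzyme A synthesis did not pass the test, with log2 differences of 0.12 and -0.18 for the pair of Ppcs probe sets, 0.01 for Dpck and -0.21 for Ppat-Dpck. The level of tim (timeless), a core clock gene, differed between strains by 0.07 ± 0.12 (SE), which did not pass (adjusted p = 0.702); a second tim probe set differed by 0.36 ± 0.14 without passing (adjusted p = 0.15).

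The comparison of ZT15 with ZT3 in controls asked which transcripts differed between the 2 times of day. The 3 largest rises among the named genes were in clock genes. The transcript of vri, a repressor of Clk, rose 8.15-fold (log2 difference 3.03 ± 0.19 SE, adjusted p = 0.00195, n = 2 and 2), per rose 6.42-fold (2.68 ± 0.095) and tim rose 6.39-fold (2.68 ± 0.14). A second tim probe set rose 4.03-fold (2.01 ± 0.16), and the mean over both gave 2.34. Pdp1, an activator of Clk, rose 2.00-fold, and cwo, a further clock repressor, differed by 0.65 without passing (adjusted p = 0.186). Of the genes with morning-phase transcripts, Clk fell by 1.37 and cry, which encodes a blue-light photoreceptor, fell by 1.08 on the log2 scale. Of 18769 probe sets, 132 passed, 59 higher and 73 lower at ZT15, and 54 of these changed at least 2-fold. After subtraction of each array's median the split was 76 higher and 66 lower, after quantile normalization 40 and 61, and after cyclic loess 37 and 67.

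**Figure D1:**
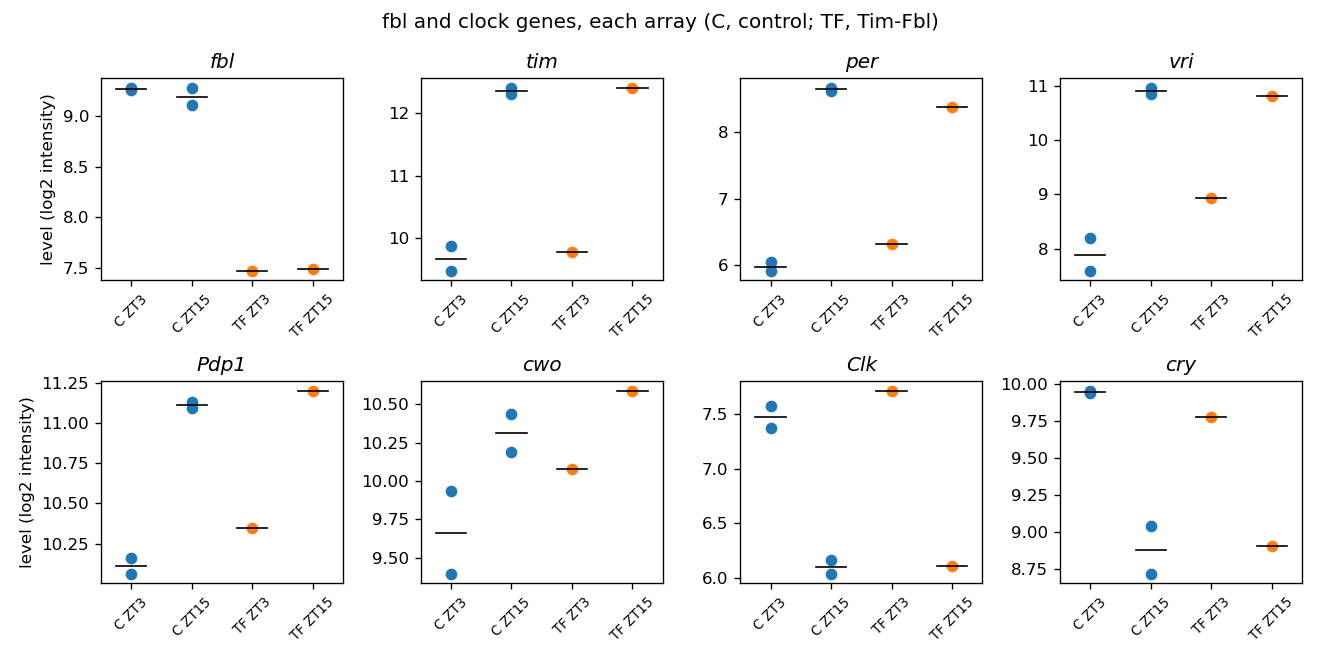
Level (log2 intensity) of fbl and of 7 clock genes on each array, with a point per array and a line at each group's mean; C is control (2 arrays per time) and TF is Tim-Fbl (1 array per time). The level of fbl was 7.47 and 7.49 on the Tim-Fbl arrays, below all 4 control arrays, and tim was higher at ZT15 in both strains.

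Outside the core clock, Usp8, a ubiquitin protease, rose 4.68-fold, gol, a ubiquitin ligase, rose 4.32-fold, and CG2681 rose 3.76-fold. Myo28B1, an unconventional myosin, rose 3.61-fold, followed by CG14221, M7BP and mdu at 2.82-fold to 3.34-fold. CG42329 was 5.75-fold lower at ZT15, CG34134 4.74-fold, CG10513 4.58-fold and Ugt35B1, a UDP-glycosyltransferase, 4.17-fold. Cdc6, a replication licensing factor, fell by 2.00 on the log2 scale, and Hr38, a nuclear receptor gene switched on by neuronal activity, was 2.85-fold lower. CG13305, CG10184 and CG15196 were lower by 3.12-fold to 3.72-fold. The lower group of CG14221, Cdc6 and CG15196 had a mean log2 under 5, near the floor, so their changes are lower bounds. Without control ZT3 replicate 2, Pdp1 (0.95), CG10513 (-2.26), CG10184 (-1.60) and CG15196 (-1.34) did not pass; CG10513 and CG10184 did not pass without control ZT3 replicate 1 (-2.13 and -1.92) either, and the mean over its probe sets gave M7BP 0.47 (adjusted p = 0.114). After quantile normalization, cyclic loess or with robust variances CG10184 (adjusted p = 0.0637, 0.0606 and 0.109) and CG15196 (0.0637, 0.0551 and 0.0622) did not pass, nor did CG10513 with robust variances (0.0502). CG10184 also did not pass with probe sets under a mean log2 of 5 or 7 left out (0.0649 and 0.0555) or in the additive model (0.0988).

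Among the 28 measured rhythmic head output genes, 3 rose, 5 fell and 20 did not pass, and adjusted over the list alone 7 rose and 11 fell. Slob, which binds a potassium channel, rose by 1.40 ± 0.090 (SE) on the log2 scale in this list. Of the evening-phase clock genes, 4 of 5 rose, and all 5 when adjusted over the list alone. As sets, camera at the preset correlation called 10 of 26 lists. The evening-phase clock genes (median 2.68, adjusted p = 9.40e-09) and the neuronal markers (median 0.22, adjusted p = 0.00144) were higher at ZT15. With an estimated correlation these gave adjusted p = 0.603 and adjusted p = 0.604. The first is large although 5 of 5 evening-phase genes were higher, as 2 residual degrees of freedom and an estimated correlation of 0.851 leave that test little power. No neuronal marker passed on its own, and cac, a calcium channel gene, differed by 0.45 (adjusted p = 0.157).

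Lists lower at ZT15 were oxidative phosphorylation (median -0.12, adjusted p = 4.13e-05) and glycolysis and gluconeogenesis (median -0.19, adjusted p = 0.000807). They gave adjusted p = 0.507 each with an estimated correlation. Of 43 and 19 measured members none passed, and adjusted over the list alone 0 and 5 fell; Pgk, a glycolytic kinase, differed by -0.44. Glutathione and antioxidant defence was also lower (median -0.10, adjusted p = 0.00263; adjusted p = 0.507 with an estimated correlation), and in it GstD10, a glutathione transferase, fell by 1.00, with 3 falls when adjusted over the list alone. The immune list (median -0.28), the proteasome (-0.06), the ovary and eggshell markers (-0.11), the rhythmic output genes (-0.14) and the gut markers (-0.10) had adjusted p between 0.0183 and 0.0466. With an estimated correlation they gave adjusted p = 0.827, 0.827, 0.604, 0.604 and 0.683. No member of the immune, proteasome, ovary or gut lists passed, over all probe sets or adjusted over the list alone. The gut list had a median below 0 and a mean of 0.03, and 19 of its 28 members lay under a mean log2 of 5, as did 15 of 21 ovary and eggshell markers. Leaving out control ZT3 replicate 1 or 2 or control ZT15 replicate 1 gave 72, 27 and 340 probe sets in place of 132, and cry did not pass without either control ZT3 array. The proteasome list lost its call without control ZT3 replicate 1 (median -0.04) or control ZT15 replicate 2 (median 0.03, the opposite sign), and the immune list without control ZT3 replicate 2 (-0.08) or control ZT15 replicate 2 (-0.04). Without control ZT15 replicate 2, 6 lists were called in place of 10. The rhythmic output, gut and ovary calls were lost after quantile normalization (medians -0.09, -0.04 and -0.05) and cyclic loess (-0.13, -0.05 and -0.05), and the gut and ovary calls also with probe sets under a mean log2 of 5 left out, at medians of -0.09 and -0.15. Without control ZT15 replicate 2 the rhythmic output and gut medians were -0.07 and -0.06, and without control ZT3 replicate 2 the gut and ovary medians were -0.07 and -0.06, none of them called. The rhythmic output call was also lost without control ZT3 replicate 1 (-0.17), and the gut and ovary calls without control ZT15 replicate 1 (-0.13 and -0.10).

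The comparison of Tim-Fbl with control asked which transcripts differed between strains on average over both times. The largest measured rise was in esg (escargot), a Snail-family transcription factor known from stem and imaginal cells, at 273-fold or more (log2 difference 8.09 ± 0.16 SE, adjusted p = 1.97e-06). Its level was 12.45 and 12.38 on the Tim-Fbl arrays, against 4.28 ± 0.040 and 4.37 ± 0.44 (SD, n = 2) in controls at ZT3 and ZT15. The largest measured fall was in Cyp6a17, a cytochrome P450 gene, which was 55.8-fold or more lower (-5.80 ± 0.14, adjusted p = 4.08e-06). Control esg and Tim-Fbl Cyp6a17 (4.01 and 3.77) lay near the arrays' lower quartiles, 3.99 to 4.16, where signal is close to the floor, so both folds are lower bounds. The close paralog of Cyp6a17, Cyp6a23, named after its value was seen, rose by 0.56 ± 0.13 (adjusted p = 0.0383), and the probes of such copies can share signal. Of 18769 probe sets, 1650 passed, 1021 higher and 629 lower, and 189 of these changed at least 2-fold. After subtraction of each array's median the split was 1239 higher and 477 lower, after quantile normalization 689 and 593, and after cyclic loess 770 and 581.

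Other rises were in AttD, an attacin antimicrobial gene (27.3-fold, log2 difference 4.77 ± 0.56), Srg2 (17.5-fold), CG10814 (16.1-fold) and LysX, a lysozyme gene (15.1-fold). Lcp65Ac and Edg91, which encode cuticle proteins, rose 9.95-fold and 5.28-fold, and CG4269, CheA87a and Phk-3 rose 5.39-fold to 6.22-fold. Lower in Tim-Fbl were Pdh, a retinal pigment cell dehydrogenase (14.7-fold), Osi6 (12.9-fold), CG7365 (11.3-fold) and Cyp4d21 (10.9-fold). The gene se (sepia), an enzyme of red eye pigment synthesis, was 7.89-fold lower, GstE14 6.29-fold and Cyp313a1 6.67-fold, with CG4842 and CG7906 at 9.82-fold and 8.16-fold. In Srg2, Osi6, CG7365 and CG7906 the lower strain had levels under a mean log2 of 5, so their folds are lower bounds and their order is not settled. Cyp4d21 on the Tim-Fbl ZT3 array (4.35) and LysX in controls at ZT15 (4.95) also lay under it, so their folds may be too low. With robust variances AttD, LysX, Osi6 and Cyp4d21 did not pass, at adjusted p of 0.0689, 0.0765, 0.0634 and 0.187. No clock gene of either phase passed; vri differed by 0.47 ± 0.26 (SE) and per by 0.04 ± 0.14.

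**Figure D2:**
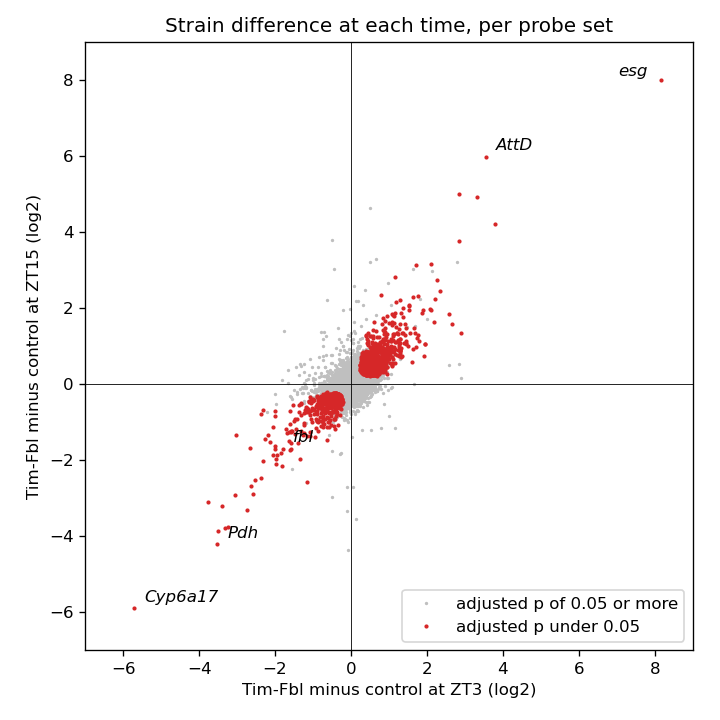
Tim-Fbl minus control mean (log2) at ZT3 on the horizontal axis and at ZT15 on the vertical axis, a point per probe set, with those of adjusted p under 0.05 for the strain effect in red. The named genes include esg at 8.17 and 8.02 and Cyp6a17 at -5.71 and -5.90, and the correlation over all probe sets was 0.662.

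Camera called 13 of 26 lists for the strain effect. Oxidative phosphorylation was lower (median -0.19, adjusted p = 4.76e-09; adjusted p = 0.356 with an estimated correlation): 4 of 43 members fell, as also when adjusted over the list alone, among them ND-19 (-0.38 ± 0.075), and 39 did not pass. Fatty acid breakdown was lower (median -0.36, adjusted p = 0.00159; adjusted p = 0.497 with an estimated correlation): 5 of 13 fell, including AkhR, the adipokinetic hormone receptor (-0.67), and CPT2, a carnitine transferase (-0.49), and adjusted over the list alone 8 fell and 1 rose. In glycolysis and gluconeogenesis (median -0.26, adjusted p = 0.000308; adjusted p = 0.497 with an estimated correlation) Hex-C and PCB fell by 0.44 and 0.39, Hex-A rose by 0.58 and 16 did not pass, with 10 falls and 1 rise adjusted over the list alone. Of the cytochrome P450 genes 5 rose, 9 fell and 35 did not pass (median -0.10, adjusted p = 0.0285; adjusted p = 0.497 with an estimated correlation), with 8 and 13 adjusted over the list alone. The call was lost without control ZT3 replicate 2 (median -0.05), control ZT15 replicate 2 (-0.07) or Tim-Fbl ZT3 (-0.06). In this list Cyp6a2 fell by 2.53 and Cyp6d2 by 1.56. Of the rhythmic output genes 0 rose and 7 fell (median -0.05, mean -0.55, adjusted p = 0.0205; adjusted p = 0.497 with an estimated correlation), with 8 falls adjusted over the list alone, including Pdh and CG2121 (-2.42).

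Immune genes were higher (median 0.70, adjusted p = 0.00159; adjusted p = 0.497 with an estimated correlation): 5 of 20 rose, including AttD, the NF-kappaB factor gene Rel (0.90 ± 0.098) and pirk (0.87), and 15 did not pass, the same counts as adjusted over the list alone. The list's call was lost without the Tim-Fbl ZT15 array, the array with the high spike-in signal, where the median was 0.11 (adjusted p = 0.388), and with probe sets under a mean log2 of 7 left out (median 0.57, adjusted p = 0.0629). Activity-regulated genes were higher (median 0.23, adjusted p = 0.00367; adjusted p = 0.497 with an estimated correlation), with 5 of 12 rising, 6 adjusted over the list alone; Atf3 rose by 0.74, Hr38 by 0.63, kay by 0.52 and Jra by 0.60. The neuronal markers were not called (camera adjusted p = 0.0861). Their median was 0.12, with 17 of 22 above 0 and 2 rising, 4 adjusted over the list alone. Neuropeptides (median 0.16), muscle markers (0.13), heat shock genes (0.22) and iron handling (0.20) were higher at adjusted p between 0.0162 and 0.0438, each with adjusted p = 0.497 with an estimated correlation. Of their members 4 of 29, 5 of 19, 3 of 10 and 1 of 15 rose, and 6, 6, 4 and 2 adjusted over the list alone, where 1 neuropeptide gene and 1 muscle marker fell; over all probe sets the neuropeptide gene Nplp3 fell by 1.58. In them Nplp4 rose by 1.01, Act88F, a flight muscle actin, by 1.31, Hsp27 by 0.58 and Zip99C, an iron transporter, by 0.96. The muscle and heat shock calls were lost without the Tim-Fbl ZT15 array (medians 0.10 and 0.19), and the neuropeptide and iron calls without the Tim-Fbl ZT3 array (0.05 and 0.08). With probe sets under a mean log2 of 5 left out, where the median of all kept probe sets was 0.07, none of these 4 lists was called (adjusted p = 0.0652, 0.13, 0.13 and 0.13), at medians of 0.17, 0.14, 0.22 and 0.20. The muscle call was also lost without either first control replicate (0.13 at ZT3, 0.09 at ZT15), the heat shock call without control ZT3 replicate 2 (0.26), and the iron call without control ZT3 replicate 1 or 2 or control ZT15 replicate 2 (0.15, 0.17 and 0.22). The iron call was lost after quantile normalization (0.15, adjusted p = 0.0718) and cyclic loess (0.15, adjusted p = 0.0966), and the heat shock call after cyclic loess (0.20, adjusted p = 0.065). With probe sets under a mean log2 of 7 left out the muscle, heat shock and iron lists were not called either (0.14, 0.19 and 0.20).

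The gut markers (median -0.15, mean -0.01, adjusted p = 0.0305) and the ovary and eggshell markers (median -0.16, adjusted p = 0.0395) were lower, each with adjusted p = 0.497 with an estimated correlation. In the gut list LysX rose and epsilonTry fell by 0.31. In the ovary list grk and CycB rose by 0.57 and 0.44, while Cp15 and bcd fell by 0.38 and 0.31. Adjusted over the list alone, 1 rose and 6 fell in the gut list and 2 rose and 6 fell in the ovary list. Both lists lost their call after quantile normalization (-0.07 and -0.06), after cyclic loess (-0.07 and -0.07), with probe sets under a mean log2 of 5 left out (-0.22 and -0.21, larger than with all members), without either Tim-Fbl array, and without control ZT3 replicate 2, where 8 lists were called in place of 13. Of the lists that camera did not call, the glial markers (adjusted p = 0.123, and 0.0247 by fry) had 4 of 12 rise, including the GABA transporter gene Gat (0.54), and 7 rise and 1 fall adjusted over the list alone. The eye pigment genes had 2 rise and 3 fall, and glutathione defence had 4 rise and 3 fall, with GstD2 at 1.51. Fatty acid and triglyceride synthesis had 4 rise and 0 fall, 5 and 0 adjusted over the list alone, with a median of -0.04. Sugar-sensing and starvation response had 2 rise and 1 fall. No measured member of the proteasome, the cytosolic ribosomal proteins or the male accessory gland and testis markers passed. The male markers were 30 of 31 under a mean log2 of 5.

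At ZT3 alone 480 probe sets passed and at ZT15 alone 395, and 236 passed at both. The strain differences at both times, which share no array, correlated at r = 0.662 and rho = 0.556 across probe sets. All 1650 probe sets past the strain test, which averages both times, had the same sign at both. That test counts a disagreement between times as residual spread, so opposite signs could hardly pass and this is no separate check. Without control ZT3 replicate 1, control ZT15 replicate 1, Tim-Fbl ZT3 or Tim-Fbl ZT15 the strain count was 893, 792, 395 and 480, and Cyp4d21 did not pass in any of these 4 fits.

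The time difference within Tim-Fbl, the difference of 2 single arrays, was set beside that of controls. The transcripts of tim, per and vri were higher at ZT15 by 2.62, 2.07 and 1.86 in Tim-Fbl, against 2.68, 2.68 and 3.03 in controls. The interaction did not pass for any clock gene, at -1.16 ± 0.33 (SE) for vri (adjusted p = 0.842) and -0.61 ± 0.16 for per (adjusted p = 0.842). Of the 5 evening-phase clock genes 0 had an interaction above 0, and 2 passed downward adjusted over the list alone (camera adjusted p = 0.0588 at the preset correlation). Simulated 2-fold interactions were found in 8.66%, so a smaller time difference in Tim-Fbl is not excluded. Of the 132 probe sets past the time test, 114 had the same sign in Tim-Fbl and 18 the opposite, while 57.5% of all probe sets had the same sign. Their median absolute log2 difference was 0.88 in controls, where they were selected and sizes are therefore raised, and 0.52 in Tim-Fbl. Over all probe sets the time differences of both strains correlated at r = 0.288 and rho = 0.238.

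The interaction asked whether the strain difference changed with time. The largest was edin, a gene induced by infection, with Tim-Fbl 3.80 log2 units above control at ZT15 and -0.51 from it at ZT3 (interaction 4.30 ± 0.36 SE, adjusted p = 0.0282), and it did not pass with robust variances (adjusted p = 0.121). In edin, CG11353, CG13043 and CG33474 some groups lay under a mean log2 of 5, near the floor. CG11353 (2.71), the cuticle protein genes Cpr100A (2.15) and Cpr62Bc (2.06), and CG13043 (2.14) passed in the same direction, as did a probe set with no symbol (1.92, singled out after its value was seen). Cpr62Bc did not pass with a variance trend (limma adjusted p = 0.0511) or with 1 test per gene (0.0569). CG33474 passed in the other, at -2.73 ± 0.22. In all 7 of 18769 passed, and 1014 had an unadjusted p under 0.05. Values that did not pass included CecB, a cecropin gene (3.48), CG7214 (3.16), CG14191 (2.65), AttD (2.44), LysX (2.17), CG11825 (-2.31), Prx6c (-2.08), MsrA (-1.42), CG8112 (-1.41), scpr-C (-1.20), Cipc (-1.07), BBS9 (-1.02) and Sobp (-0.95).

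As a list, immune genes had an interaction median of 0.61 (adjusted p = 5.04e-07; adjusted p = 0.816 with an estimated correlation). Their median strain difference was 0.11 at ZT3 and 0.92 at ZT15, and only edin of the 20 passed alone, over all probe sets and adjusted over the list alone. Its Tim-Fbl values at ZT15 come from the 1 array whose spike-in median lay 1.33 log2 units above the control mean. Glycolysis and gluconeogenesis had a median of 0.23 (adjusted p = 0.00134) and phototransduction of -0.21 (adjusted p = 0.00182), each with adjusted p = 0.816 with an estimated correlation. No member of either passed over all probe sets, and 1 and 0 passed adjusted over the list alone. Pepck1, an enzyme of gluconeogenesis, had 1.36 and the eye gene inaD had -0.65. The median time difference of the glycolysis list was -0.19 in controls and -0.05 in Tim-Fbl. Its interaction holds that control fall with its sign turned, so it is no separate observation. With limma, 0 probe sets passed after quantile normalization (1079 at an unadjusted p under 0.05) or cyclic loess (1105), and 0 with probe sets under a mean log2 of 5 (596) or 7 (445) left out. Without control ZT3 replicate 1 or 2 or control ZT15 replicate 1 or 2 the counts were 2, 0 (956 at an unadjusted p under 0.05), 57 and 31, and 7, 3, 6 and 7 lists were called in place of 3.

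**Figure D3:**
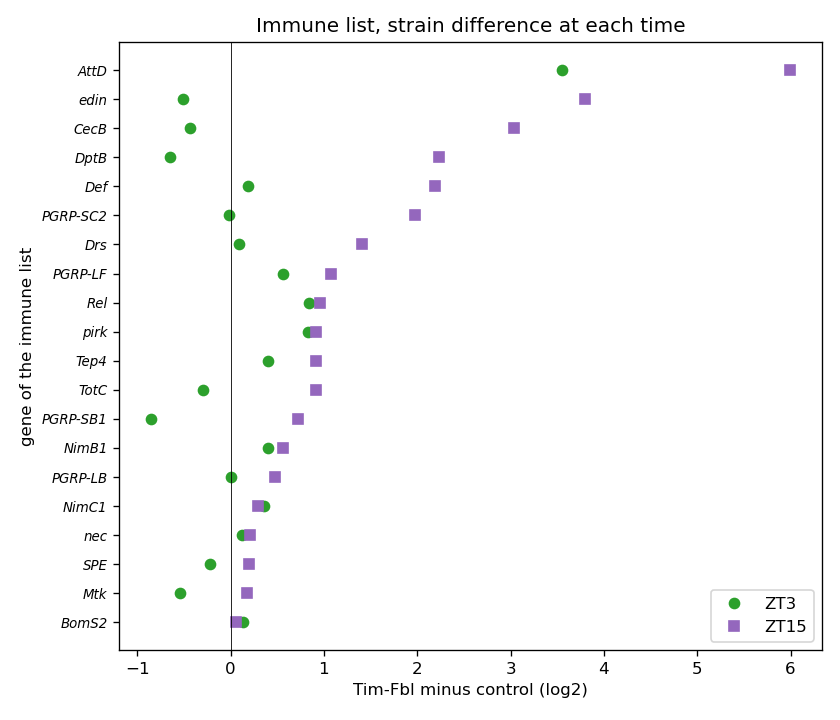
Tim-Fbl minus control mean (log2) for the 20 measured genes of the immune list, with circles for ZT3 and squares for ZT15, each from 1 Tim-Fbl array and 2 control arrays. The medians were 0.11 at ZT3 and 0.92 at ZT15, and edin lay at -0.51 and 3.80.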

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

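The tests of the esg neighbourhood and arrays, the immune list and the neighbouring genes under the time effect were chosen after the results had been seen, and the bound for the last of these replaced a stricter one after its value was seen; under the stricter bound that value would not have counted against linked background.

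The strain difference at ZT15 differed from that at ZT3 for 7 probe sets by limma's interaction test: edin (4.30), CG11353 (2.71), Cpr100A (2.15), CG13043 (2.14), Cpr62Bc (2.06), a probe set with no symbol (1.92) and CG33474 (-2.73). It also differed for the immune (median 0.61), glycolysis (0.23) and phototransduction (-0.21) lists by camera at the preset correlation. The glycolysis value holds that list's fall at ZT15 in controls with its sign turned, so it is no separate observation. With an estimated correlation 0 lists were called, but few residual degrees of freedom left hardly any list able to pass. Outside the fly transcripts, the poly-A spike-in controls on the Tim-Fbl ZT15 array lay 1.33 log2 units above the control mean.

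For the immune genes at ZT15 in Tim-Fbl, relatively more spike-in signal could mean that less fly RNA entered the labelling on that array. Lists matched on mean level bear only on a shift shared by genes of that level. The medians of 10000 such random lists had a median of -0.0731 and a highest value of 0.209. The immune median was 0.614, at percentile 100, so a shift shared by genes of that level would not give all of it. The immune list was picked for its large interaction, so a high percentile was likely from the start and is no separate check. Other effects of less fly RNA on that array were not tested and stay open. The matched lists held random genes, while the immune genes varied together (estimated correlation 0.429). The percentile therefore says nothing on an event that moved the immune genes jointly. More fat body, an organ that makes antimicrobial peptides, stays open. The fat body markers' median interaction was -0.0026, but 9 of 12 lay in the top 5% of probe sets by level (Yp2 and Yp3 at 14.4), where a small added share would not show, and Lsp2 had 1.88 without passing. Only 1 Tim-Fbl sample was taken at ZT15, so an infection or another event in that sample and an effect of the strain cannot be told apart.

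For esg in Tim-Fbl, a faulty array is argued against by its 2 arrays, which differed by 0.07 log2 units. Raised transcription of the whole neighbourhood is argued against by the median of -0.0367 over the 10 nearest measured genes, 5 on each side in the RefSeq order of Release 6 plus ISO1 MT, none of which passed. What else differs at esg between the strains stays open and was not tested.

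For the strain effect, the 9 choices of 1 array per time gave 1650 probe sets for the real choice and at most 0 for the others (157 to 874 at an unadjusted p under 0.05), and 9 choices are too few for a share under 0.05; the real choice was the 1 with as many. A difference in genetic background between strains may alter linked genes together. Among 11894 placed genes, 104 neighbouring pairs with different symbol stems passed in the same direction. In 10000 permutations within chromosomes the median was 70 and the highest 101, so the pairs lay at percentile 100. Genes named only by a CG or CR number each counted as their own stem, so related neighbours among them were not left out. The time effect in controls, where no strain differs, was given as many genes, the 1257 with the smallest p, although only 120 passed. It also gave an excess, 86 pairs against a median of 69 and a highest of 98 (percentile 98.5). The excess was smaller than for the strain calls, at 1.25 against 1.49 times the permutation median. Genetic background and any other difference of the Tim-Fbl strain therefore cannot be told apart here, since they vary together and neighbouring genes can share regulation.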

How the results depend on the processing

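The alternatives for gene lists other than the filter at 5, the mean over probe sets, the estimated correlation and fry were added after seeing the data. The lower level of fbl in Tim-Fbl and the rise of tim kept their direction and passed under every alternative run. The time effect's count, 132, became 83 and 75 without probe sets under a mean log2 of 5 and 7, 214 with robust variances and 27 to 340 without single arrays. The strain effect's count, 1650, became 594 with a fold of at least 1.5, 480 at ZT3 alone, 395 at ZT15 alone and 395 to 1255 without single arrays. The interaction's count, 7, became 0 under both filters, quantile normalization and cyclic loess, and 0 to 57 without single arrays. The replicate numbers of the control arrays did not pair them (r = 0.038 between the replicate differences at ZT3 and ZT15, from 2 pairs); with the number as a block the counts were 334 for time, 1212 for strain and 23 for the interaction, and 8, 13 and 5 lists. Lists called numbered 10, 13 and 3 for time, strain and interaction. The numbers were 0, 0 and 0 with an estimated correlation (0, 1 and 0 at an unadjusted p under 0.05) and 0, 6 and 0 with fry (7, 11 and 2 unadjusted), which kept 5 of camera's 26 calls over the 3 comparisons and added the glial markers for strain. The test with an estimated correlation had too few residual degrees of freedom to call almost any list. Some lists, such as the immune list, also had an estimated correlation far above the preset. With the filter at 5 there were 7 for strain and 5 for the interaction, with the filter at 7 there were 5 for the interaction, and with the mean over probe sets 6. Without single arrays the lists numbered 6 to 9, 8 to 12 and 3 to 7. With control ZT3 array 2 and ZT15 array 1 or 2 alone, the agreement of the strain effect was 0.567 and 0.542 and that of the time effect 0.182 and 0.209. The sign changed for the median of the proteasome list's time effect, 0.030 without control ZT15 replicate 2, and for clock gene and fbl values that passed in neither setting: per strain effect -0.038 (quantile), -0.058 (loess), -0.033 (without control ZT3 replicate 2) and -0.26 (ZT15 alone), with 0.345 as the highest without an array; tim strain effect -0.016 (highest 0.156) and interaction 0.14 (lowest -0.262) without control ZT3 replicate 2, and interaction 0.016 (quantile) and 0.0071 (loess); cwo interaction 0.13 (lowest -0.408) without control ZT3 replicate 2; the second cwo probe set's strain effect -0.099 without control ZT3 replicate 2 and -0.21 at ZT15 alone (highest 0.515); vri strain effect -0.11 (highest 1.05) and cry 0.030 (lowest -0.173) at ZT15 alone; fbl time effect 0.0031 without control ZT15 replicate 2 (lowest -0.16). The cause was not tested, except that the filters and left-out arrays test fewer probe sets or fewer samples. Of the 26 list calls over the 3 comparisons, the number lost was 1 after median subtraction, 6 after quantile normalization, 7 after cyclic loess and 8 with the filter at 5. The small number of arrays, and for dim probe sets the signal near the floor, limit all of these.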

Other observations

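All tests in this part were chosen after the data had been seen, as 6 families picked by symbol, and they are given as values. A mean log2 of at least 5 was reached by 38 of 66 cuticle, 17 of 35 UDP-glycosyltransferase and 26 of 47 odorant-binding protein genes. Of 66 measured cuticle protein genes of the Cpr family, 3 rose and 6 fell in Tim-Fbl, with Cpr72Ec at -2.19, Cpr49Ae at -1.83 and Cpr11B at 1.74 on the log2 scale. Their median was -0.14 (camera adjusted p = 0.0013 at the preset correlation, p = 0.121 with an estimated correlation), and it stayed below 0 after median subtraction (-0.11), quantile normalization (-0.10) and cyclic loess (-0.098). Their interaction median was 0.05 (camera adjusted p = 0.000705, p = 0.147 with an estimated correlation). Of the 66 interactions 40 were above 0, and 2 passed upward and 0 downward. Of 69 mitochondrial ribosomal protein genes 3 fell and none rose, and 6 had a value above 0. Their median was -0.13 (adjusted p = 1.48e-07, p = 0.193 with an estimated correlation), and it was -0.10, -0.22 and -0.24 under the same 3 scalings, with 1, 13 and 18 genes fallen. Of 35 UDP-glycosyltransferase genes 4 fell at ZT15 in controls, with a median of -0.15 (adjusted p = 6.31e-06, p = 0.0316 with an estimated correlation) that was -0.11, -0.15 and -0.13 under the 3 scalings, with 2, 3 and 3 genes fallen. Their median time difference in Tim-Fbl was 0.01, and their interaction median was 0.24, with 29 of 35 above 0 (p = 0.0331 with an estimated correlation, not adjusted), and no gene passed. The interaction holds the same control difference with its sign turned, so it is no separate observation. In Tim-Fbl 6 odorant-binding protein genes fell and 0 rose (p = 0.147 with an estimated correlation); after median subtraction 5 fell and 2 rose, after quantile normalization 8 and 0, and after cyclic loess 8 and 1. The Turandot and chitin-related families had p = 0.268 and 0.552 for the strain effect with an estimated correlation.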
